A study of Rattus norvegicus with 5 samples.

How the data were processed

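Laser-captured neurons of the rat striatum were profiled by RNA sequencing in 5 libraries. The neurons had been marked by fluorescent tracer carried back from the region their axons reach, and the cell type in the labels set the group. Striatomesencephalic neurons project to the midbrain and make up the direct pathway (2 libraries). Striatopallidal neurons project to the pallidum and make up the indirect pathway (3 libraries). Per the labels' protocols, captured cells were lysed in TRIzol, polyadenylated RNA was reverse transcribed with a single-cell amplification kit (REPLI-g), and libraries were made with the GeneRead kit. The number of cells and animals behind each library is not given in the sources used here, and neither is whether libraries of one group came from separate animals. If some share an animal, p-values are too small. P-values of single genes measure only the spread between these 5 libraries.

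Per the submitters' processing notes, TopHat2, HTSeq, edgeR and limma were used with genome build Rnor_6.0. Their versions and roles are not given in the sources used here. The authors deposited 1 table of read counts per gene for each library, with 32285 Ensembl gene identifiers, and these counts were the input of every test here. A table of normalized values deposited by the authors holds a signal per gene, equal to the count divided by the normalization factor in the labels to within 0.00572. A table deposited by the authors as CPM (counts scaled to a common library total) equals that signal divided by its column sum, to within 0.00522. The authors' deposited comparison gives a log2 fold change, a log2 mean level, a p-value and an adjusted p-value for each of 12054 genes. No genome or annotation of build Rnor_6.0 was used here, so no positions are given. Gene symbols were taken from the authors' deposited comparison, which pairs all but 15 of its 12054 identifiers with a name. Of the genes tested, 11904 had a symbol and 1907 had none.

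Library totals were 20845178 and 22614680 counts in striatomesencephalic replicates 1 and 2. They were 23843228, 24805062 and 22413168 counts in striatopallidal replicates 1, 2 and 3. At these depths 3 counts, taken as the detection floor, correspond to 0.121 to 0.144 CPM. Reads carried no molecular identifiers, so this floor covers counting error only. Chi-square values per degree of freedom between libraries ran from 164 to 585, far above 1, and no library was taken for a repeat of another.

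Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the groups, libraries were scaled by TMM, and glmQLFit and glmQLFTest were run with their defaults on all 5 libraries. The Benjamini-Hochberg threshold was 0.05. Fold changes are log2 values of striatomesencephalic minus striatopallidal libraries, each with a standard error obtained from the fold change and its F statistic. CPM values given with an SD are TMM-scaled. Sums over marker lists are plain CPM. With 2 libraries against 3, an exact two-sided permutation test of a single value cannot give a p below 0.1, so none was used.

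Before the data were examined, 32 gene lists were fixed, covering pathway and compartment markers, other cell types, receptors, channels, signalling, synapse, stress and housekeeping functions. Symbols were matched without regard to case. Members whose symbol is absent from the authors' deposited comparison could not be matched and were not tested. The 29 lists with at least 5 tested members were compared by camera (limma 3.58.1) on voom values with a preset inter-gene correlation of 0.01, adjusted over the 29 lists. Camera with an estimated correlation and fry stand beside it. With an estimated correlation, camera also takes its degrees of freedom from the 5 libraries and not from the genes. Fry asks whether the genes of a list move, on balance, one way, and its mixed form whether they change in either direction. Named genes followed a rule fixed at the same time: all tested pathway markers, the 5 genes per direction with the smallest p where none passed, the 5 or 3 members of each list with the smallest p, and the 5 most abundant genes of each group. Some genes that this rule takes are not reported here.

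Both steps were tested on simulated counts with the means and depths of these libraries. With the spread of these libraries, 0 of 98 genes changed 4-fold and 31 of 95 genes changed 16-fold were recovered among 13405 genes, and 1 unchanged gene was called. With a dispersion of 0.02 in place of that spread, 97 of 99 genes changed 4-fold and 97 of 97 genes changed 16-fold were recovered among 13628 genes, with 6 unchanged genes called. A 2-fold change of 12 direct pathway genes passed the set test in 18 of 20 simulations on 13811 genes, and no change passed in 0 of 20. Genes were drawn independently there, so these simulations cannot show how the set test behaves where genes vary together. The direct list itself had an estimated correlation of 0.201, above the preset 0.01.

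Alternatives fixed before the data were examined were 5 other scalings, 3 other filters, 6 other tests (DESeq2 1.42.0, limma voom with and without quality weights, the exact test of edgeR, and 2 other settings of the quasi-likelihood fit), an adjusted p of 0.1, the replicate number as a block, thinning to the shallowest library, and leaving out each library in turn. Leaving out a striatomesencephalic library leaves 1 in that group, whose spread is then assumed to be that of the striatopallidal libraries. Added after the data were examined were voom on the authors' gene set with the label factors applied and without them, and the striosome list without genes of the direct pathway list.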

Results

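The data are gene counts from 5 samples of laser-captured neurons of the rat striatum, each neuron chosen by the tracer it had taken up from its axon's target. Direct pathway neurons, which project to the midbrain, gave 2 striatomesencephalic libraries. Indirect pathway neurons, which project to the pallidum, gave 3 striatopallidal libraries. Library totals ran from 20845178 to 24805062 counts. Whether the libraries of a group came from separate animals is not known, so p-values of single genes measure the spread between these libraries only. Camera p-values with the preset correlation set the genes of a list against the other genes and take genes as nearly independent. The 5 most abundant transcripts of each group included Pde10a, a phosphodiesterase enriched in striatal projection neurons, and Prkcb, a protein kinase C. Pde10a stood at 5061 ± 1349 CPM (SD, n = 2) in striatomesencephalic and 7358 ± 2129 CPM (SD, n = 3) in striatopallidal libraries.

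The first comparison asked whether the captured neurons carried the transcripts known for their pathway. Striatomesencephalic libraries held more RNA of direct pathway genes, and striatopallidal libraries more of indirect pathway genes. Drd1, the dopamine receptor of direct pathway neurons, stood at 945 ± 170 CPM (SD, n = 2) in striatomesencephalic libraries and 435 ± 66.9 CPM (SD, n = 3) in striatopallidal libraries, a log2 fold change of 1.12 ± 0.31 (SE). Drd2, the dopamine receptor of indirect pathway neurons, stood at 123 ± 21.2 CPM (SD, n = 2) and 510 ± 20.5 CPM (SD, n = 3), a log2 fold change of -2.05 ± 0.35 (SE). Penk, which encodes the enkephalin precursor, had the largest log2 fold change in size of the 20 markers apart from Ttc12, at 302 ± 73.7 CPM (SD, n = 2) against 1951 ± 312 CPM (SD, n = 3), or -2.69 ± 0.34 (SE) on the log2 scale. None of the 20 tested markers passed the threshold over all 13811 genes in edgeR's quasi-likelihood test, where the smallest adjusted p was 0.779. Over all genes DESeq2 called Pdyn (adjusted p = 0.0270), Lingo2 (0.0451), Drd2 (0.00532) and Penk (0.000204), and the exact test of edgeR called Penk (0.00580).

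Of 12 direct pathway markers, 10 were higher in striatomesencephalic libraries, and 4 of these passed adjusted over the list alone. Pdyn, the dynorphin precursor, rose by 1.86 ± 0.32 (SE) on the log2 scale (adjusted p over the list alone 0.00822). Tac1, the substance P precursor, rose by 1.13 ± 0.31, Lingo2 by 2.09 ± 0.54 and Drd1 as above, each with an adjusted p of 0.0254 over the list alone. The other markers with a positive value were Asic4 at 2.62, Eya1 at 2.42, Isl1 at 2.04, Slc35d3 at 0.68, Ebf1 at 0.64 and Chrm4 at 0.62. Sfxn1 and Zfp521 had negative values of -0.99 and -1.33. The Sfxn1 value rested on striatopallidal replicate 2, with 23888 counts against 2716 to 5982 in the other libraries, and it was 0.92 without that library. Chrm4 was -0.49 without striatomesencephalic replicate 2.

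The indirect list was fixed with 12 symbols, of which Gpr52, Sp9, Upb1 and Serpina9 had no match and were not tested. Of 8 indirect pathway markers tested, 7 were higher in striatopallidal libraries, and 4 of these passed adjusted over the list alone. These were Penk (0.000699), Drd2 (0.0026), Adora2a (0.00962) and Ptprm (0.03), where the numbers are adjusted p-values over the list alone. Adora2a, the adenosine receptor of indirect pathway neurons, had a log2 fold change of -1.74 ± 0.41 (SE), and Ptprm, a receptor phosphatase, -1.09 ± 0.35 (SE). Gpr6 at -1.07, Plxdc1 at -2.34 and the kainate receptor gene Grik3 at -1.08 did not pass. Ttc12 passed in the opposite direction (0.03), on 24 and 132 counts in striatomesencephalic libraries against 6, 0 and 1 counts in striatopallidal libraries.

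Tested as lists with camera, the direct pathway markers were higher in striatomesencephalic libraries (adjusted p = 4.5e-07) and the indirect pathway markers lower (adjusted p = 2.07e-07). Neither call held with an estimated correlation, where the direct list had adjusted p = 0.435 and the indirect list adjusted p = 0.270. The estimate itself was 0.201 for the direct list and -0.00538 for the indirect list. The latter lies below the preset 0.01, so a larger correlation does not account for the loss in the indirect list. That setting also takes fewer degrees of freedom, those left by the 5 libraries, which weakens the test by itself. The number of direct markers past the threshold adjusted over the list alone was 0 without striatomesencephalic replicate 1 or without striatopallidal replicate 3, and 1 without striatomesencephalic replicate 2 or without striatopallidal replicate 1. That of indirect markers, 4 lower and 1 higher in striatomesencephalic libraries when all 5 libraries were used, was 7 lower and 1 higher without striatomesencephalic replicate 1, and 3 lower and 0 higher without striatomesencephalic replicate 2 or without striatopallidal replicate 3.

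**Figure D1:**
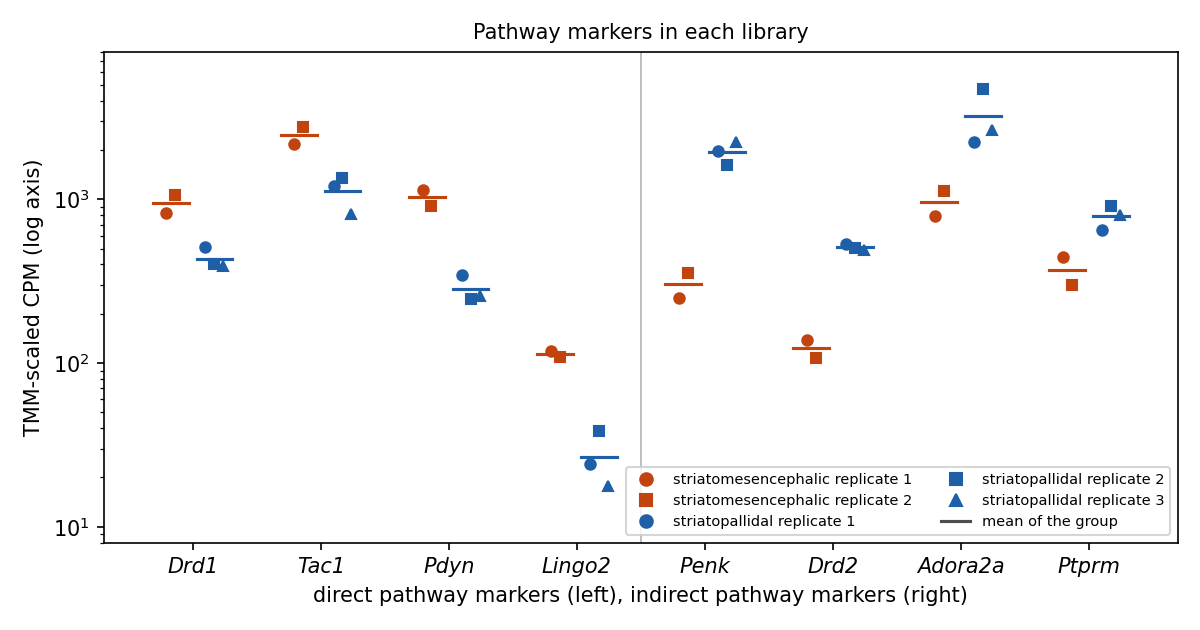
TMM-scaled CPM, on a log axis, of the 4 direct and the 4 indirect pathway markers that passed in their own pathway's direction, adjusted over each list alone. Each point is 1 library and each bar the mean of a group. Penk lies at 302 CPM on average in striatomesencephalic and 1951 CPM in striatopallidal libraries. For all 8 genes the groups do not overlap, which their selection by the test favours.

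**Figure D2:**
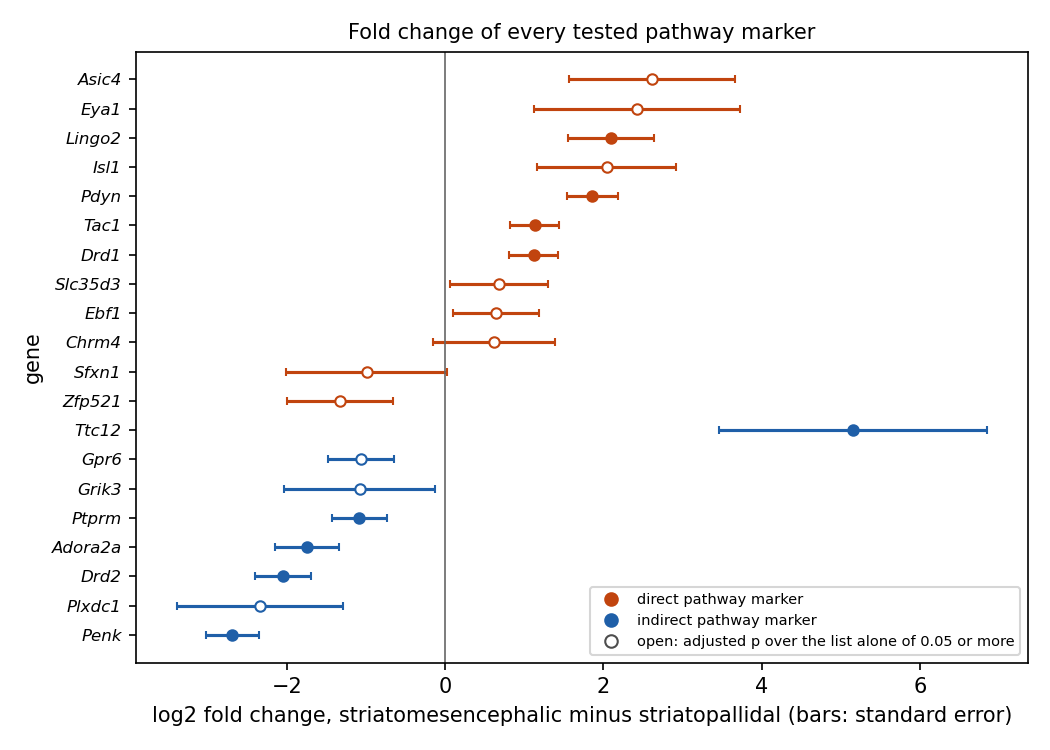
Log2 fold change of the 20 tested pathway markers, striatomesencephalic minus striatopallidal libraries, with bars of 1 standard error. Filled points have an adjusted p under 0.05 over their own list alone. Most direct markers lie to the right of 0 and most indirect markers to the left, with Sfxn1, Zfp521 and Ttc12 on the opposite side.

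The second comparison asked which genes differed between the 2 neuron types across the transcriptome. Beside the pathway markers, the smallest p-values among genes higher in striatopallidal libraries belonged to Entpd1, an enzyme that breaks down extracellular ATP, to the muscarinic receptor gene Chrm3 and to Rgs4, a regulator of G protein signalling. Entpd1 stood at 20.8 ± 1.29 CPM (SD, n = 2) in striatomesencephalic and 194 ± 45.6 CPM (SD, n = 3) in striatopallidal libraries, a log2 fold change of -3.22 ± 0.49 (SE). Rgs4 stood at 131 ± 7.03 and 590 ± 74.8 CPM, a log2 fold change of -2.17 ± 0.35 (SE). Chrm3 had 1 and 4 counts in striatomesencephalic libraries against 740, 377 and 471 counts in striatopallidal libraries. Among genes higher in striatomesencephalic libraries, Crym, a thyroid hormone binding protein, stood at 259 ± 53.6 against 41.4 ± 11 CPM, a log2 fold change of 2.65 ± 0.45 (SE). Osbpl10, an oxysterol binding protein gene, stood at 138 ± 71.4 against 10.7 ± 0.564 CPM, or 3.69 ± 0.57 (SE). Ccdc19 had 176 and 1280 counts against 1, 0 and 0, and AABR07006713.1 had 134 and 826 counts against 1, 1 and 0.

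None of these 7 genes passed with edgeR's quasi-likelihood test, while DESeq2 and the exact test of edgeR each called all 7. The 7 were picked by their small p-values on the same counts, so these calls add no separate support. Over 13811 genes, 0 passed the threshold with edgeR's quasi-likelihood test, while 839 had an unadjusted p below 0.05. Of these, 405 were higher in striatomesencephalic and 434 in striatopallidal libraries. Across the 10 groupings of the 5 libraries into 2 and 3, 4 gave as many or more, the real one included. DESeq2 called 226 genes, 87 higher and 139 lower in striatomesencephalic libraries, and the exact test of edgeR called 45, of which 31 were higher and 14 lower, all 45 being among those of DESeq2. limma voom called 0 genes. The groups did not overlap in CPM for 2981 genes, or 21.6%, where chance gives 20%. The spread behind these counts was wide, with a biological coefficient of variation of 0.822.

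Among compartment markers, genes of striosomes, the patches embedded in the striatal matrix, were higher in striatomesencephalic libraries as a list (camera adjusted p = 0.000178), and adjusted p = 0.302 with an estimated correlation. Of 10 members, 4 rose adjusted over the list alone: Pdyn, Tac1, Nnat and Lypd1. Nnat stood at 37.0 ± 4.74 CPM (SD, n = 2) against 5.85 ± 2.87 CPM (SD, n = 3), a log2 fold change of 2.66 ± 0.77 (SE), and Lypd1 had a log2 fold change of 1.65 ± 0.57 (SE). Kremen1, another striosome gene, fell by 1.46 on the log2 scale and also passed adjusted over the list alone, in the opposite direction. The list shares Pdyn, Tac1 and Asic4 with the direct pathway list, and without those genes its adjusted p was 0.161, a test chosen after the data were examined. The 8 matrix markers had a median log2 fold change of -0.33, with 2 members higher and 6 lower in striatomesencephalic libraries (camera adjusted p = 0.439). Sgk1 at -0.90 and Epha4 at -0.61 did not pass.

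Receptor genes for neuromodulators differed in both directions. Of 33 tested members, 2 were higher and 6 lower in striatomesencephalic libraries past the threshold adjusted over the list alone, and the list passed fry's mixed test, which counts changes of either direction (adjusted p = 0.0121), but not camera (adjusted p = 0.164). The list shares Drd1, Chrm4, Drd2 and Adora2a with the pathway lists and was not tested without them, so it is no separate result. Beside Drd2, Adora2a and Chrm3, the serotonin receptor gene Htr4 was lower, at 5.18 ± 4.69 CPM (SD, n = 2) against 131 ± 97.8 CPM (SD, n = 3), a log2 fold change of -4.66 ± 1.04 (SE). Among 6 metabotropic glutamate receptors, Grm8 was lower adjusted over the list alone (0.0263), at 1.72 ± 0.226 against 34.4 ± 26.1 CPM. Grm5 had 0.25 and did not pass. The list had a mixed adjusted p of 0.0317 by fry and a camera adjusted p of 0.312. Of 16 ionotropic glutamate receptors, 11 were lower in striatomesencephalic libraries with a median of -0.77, which did not pass (camera adjusted p = 0.055). Of its members, Grin2c had -2.32 and Grik4 -2.71. The 14 GABA receptors split evenly, with 7 higher and 7 lower (camera adjusted p = 0.736), and Gabra5 had 1.81.

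Potassium channel genes were lower in striatomesencephalic libraries as a list, with 28 of 38 members lower and a median of -0.82 (camera adjusted p = 0.0149). The call was lost with an estimated correlation (adjusted p = 0.435), without striatomesencephalic replicate 1 (adjusted p = 0.166) and without striatopallidal replicate 2 (adjusted p = 0.236). No member passed adjusted over the list alone. Kcnj3, an inward rectifier subunit, had -2.14 and Kcnk2, a 2-pore channel, -1.07. The 28 sodium and calcium channel genes had a median of -0.09 (adjusted p = 0.481), with Cacna1c at -1.20 and Scn4b at -0.68.

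Transcripts encoded by the mitochondrial genome were lower in striatomesencephalic libraries in 13 of 13 cases, with a median of -0.55 (camera adjusted p = 0.00153), and the median was below 0 under each of the 6 scalings tried. These transcripts varied together (estimated correlation 0.418), so the 13 are not separate agreements. Their summed CPM overlapped between the groups, at 5265 and 6608 in striatomesencephalic against 7896, 5665 and 6223 in striatopallidal libraries. With an estimated correlation the list had adjusted p = 0.566, and it had 0.166 without striatomesencephalic replicate 1 and 0.0579 without striatopallidal replicate 1. Mt-co2 had -0.80 and Mt-cytb -0.76, and no member passed adjusted over the list alone. The 54 nuclear genes of oxidative phosphorylation had a median of -0.07 (adjusted p = 0.593).

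The remaining neuronal lists did not pass the camera test. The 25 markers shared by both types of spiny projection neuron had a median of -0.09 (adjusted p = 0.155). The 21 pan-neuronal markers had a median of -0.27 (adjusted p = 0.327), and 1 of them, the synapsin gene Syn1, fell by 3.62 on the log2 scale with an adjusted p of 0.046 over the list alone. Medians were -0.07 for 56 genes of cAMP and calcium signalling (adjusted p = 0.539), where Rgs4 passed adjusted over the list alone, -0.08 for 43 synaptic vesicle genes (0.703) and -0.05 for 33 postsynaptic density genes (0.439). They were -0.17 for 43 genes of axonal transport and cytoskeleton (adjusted p = 0.168), -0.51 for 51 axon guidance genes (0.13) and 0.26 for 28 striatal transcription factors (0.13). They were 0.12 for 25 immediate early genes (adjusted p = 0.481), 0.13 for 14 genes of axon injury and neuronal stress (0.937) and 0.07 for 60 ribosomal protein genes (0.378). In the axon guidance list, Sema5a had -1.74 and Plxnd1 1.69, and neither passed.

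The libraries were also examined for RNA of other cells. Oligodendrocyte RNA was present in every library, with summed CPM over 16 markers of 7117 ± 957 (SD, n = 2) in striatomesencephalic and 6885 ± 1095 (SD, n = 3) in striatopallidal libraries, and Mbp, the myelin basic protein gene, alone reaching 2289 to 3767 CPM. Astrocyte markers summed to 2614 ± 177 and 2762 ± 359 CPM. Gfap, the filament protein of astrocytes, was the exception within its list, at 11.5 and 3.85 CPM in striatomesencephalic libraries against 243, 175 and 87.7 CPM in striatopallidal libraries, a log2 fold change of -4.56 ± 0.82 (SE) with an adjusted p of 0.0134 over the list alone. Sums were far lower for vascular markers (14 members, 330 ± 74.4 and 267 ± 17.0 CPM) and oligodendrocyte precursors (6 members, 269.8 ± 26.0 and 282 ± 82.6 CPM). The same held for microglia (9 members, 209 ± 12.9 and 204 ± 119.8 CPM) and striatal interneurons (8 members, 112 ± 4.99 and 158 ± 25.8 CPM). Blood, with 3 members, had 5.85 ± 0.272 and 24.6 ± 23.6 CPM. The oligodendrocyte and astrocyte lists had 16 members each, so these sums do not rank the amounts of RNA per cell type. Camera adjusted p-values for the lists of other cells ran from 0.439 to 0.924. Lists with under 5 tested members had no set test: in the glutamatergic list Rorb had 2.24 and Nrgn -1.61, the 3 blood genes had a median of -3.09, with 1 higher and 2 lower in striatomesencephalic libraries, and the 1 ependymal gene, Enkur, had -0.69.

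**Figure D3:**
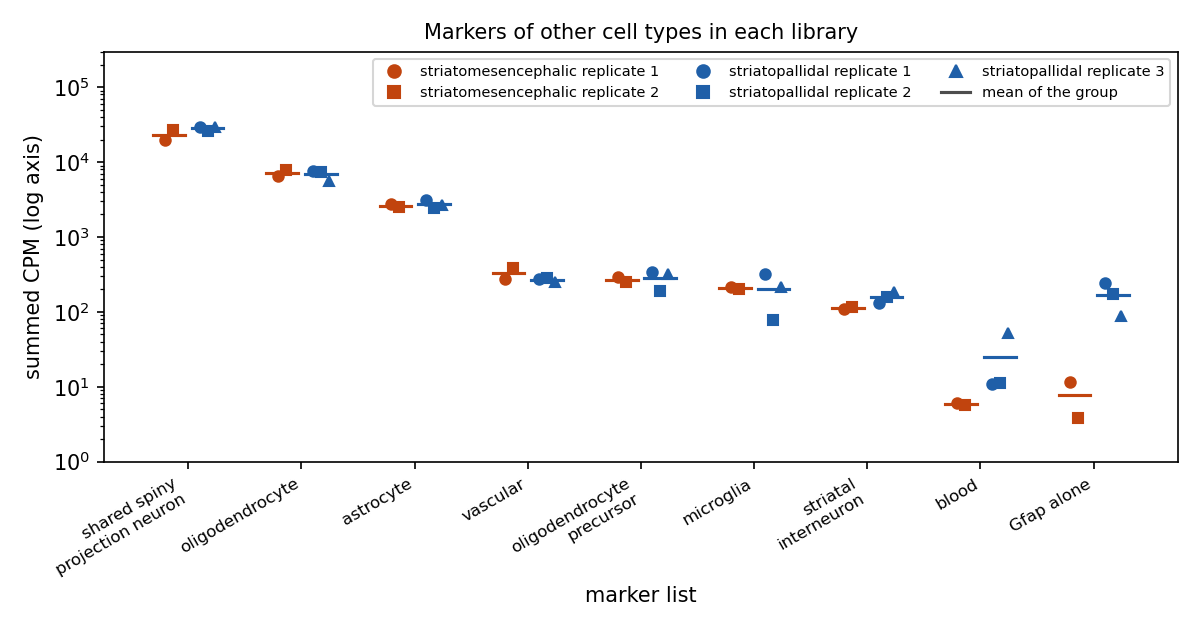
Summed CPM, on a log axis, of marker lists in each library, with Gfap alone at the right. Each point is 1 library and each bar the mean of a group. The astrocyte sums lie between 2476 and 3165 CPM in all 5 libraries, while Gfap lies at 3.85 to 11.5 CPM in striatomesencephalic and 87.7 to 243 CPM in striatopallidal libraries.

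Correlations between libraries within a group overlapped with those between groups. Genes with at least 10 counts numbered 12844 and 12886 in striatomesencephalic replicates 1 and 2, and 13969, 11871 and 13188 in striatopallidal replicates 1, 2 and 3. Across 13811 genes, which are not replicates, the Spearman correlation was 0.845 between the striatomesencephalic libraries and 0.907 between striatopallidal replicates 1 and 3, and pairs across the groups ran from 0.785 to 0.880. Striatopallidal replicate 2 correlated with the other libraries at 0.785 to 0.820, including those of its own group. Frmd6 took 2.89% of its counts, at 28862 CPM against 357 to 524 CPM in the others.

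The number of genes present in one group and wholly absent from the other depended on the threshold. With at least 10 counts in every library of one group and 0 in every library of the other, 7 genes were found in striatomesencephalic and 3 in striatopallidal neurons. With at least 1 count in place of 10 these were 97 and 115 genes, and with at least 20 counts 5 and 1. Those with a symbol were Antxr2, an anthrax toxin receptor gene (26 and 179 counts), the cyclin gene Ccnb3 (91 and 100 counts), the cytokine subunit gene Il27 (34 and 99 counts) and AABR07003001.1 (78 and 729 counts), all in striatomesencephalic neurons. They were named because the count is small, after their values were seen. The total of 10 at the threshold of 10 counts compares with 2 to 27 in the 9 other groupings of the 5 libraries into 2 and 3.

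The authors' deposited table compares the same groups over 12054 genes. It calls 0 genes at an adjusted p of 0.05, with a smallest adjusted p of 0.927. It lists 546 genes with an unadjusted p below 0.05, fewer than evenly spread p-values would give. In the authors' deposited table the 10 genes with the smallest p are Crym, Adora2a, Pdyn, Camkv, Entpd1, Zcchc12, Penk, Tac1, Serpine2 and Osbpl10, of which Crym, Pdyn, Camkv, Zcchc12, Tac1, Serpine2 and Osbpl10 are higher in striatomesencephalic libraries. The authors' deposited table gives Penk a log2 fold change of 2.55, Drd2 1.96 and Drd1 -1.24, coded as striatopallidal minus striatomesencephalic. Over the 11919 genes in both, its fold changes correlated with those of edgeR's quasi-likelihood fit at 0.902 once the sign was turned, and 88.4% had the same direction.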

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

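The voom test of the authors' gene set and the shortened striosome list were chosen after the results were seen. The count of 0 genes past the threshold held under the 5 other scalings, 3 other filters, the adjusted p of 0.1 and thinning. It also held with limma voom with and without quality weights, the robust quasi-likelihood setting and each left-out striatopallidal library. The legacy quasi-likelihood setting matched the main fit, with 839 genes at an unadjusted p below 0.05 in both, and is no separate check. The count past the threshold was 226 with DESeq2 and 45 with the exact test of edgeR. Of the DESeq2 calls, 207 were genes whose groups do not overlap. A test between the groups favours such genes, so this lends the calls no separate support. The cause of the difference between the tests was not tested.

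Direct markers past the threshold adjusted over the list alone numbered 4, and 2 with DESeq2, 7 with limma voom, 2 with the exact test and 0 to 4 without 1 library. Indirect markers numbered 5, of which 4 were lower, and 3 to 8 without 1 library, of which 3 to 7 were lower. Fewer libraries remain in those fits. The lists past the threshold numbered 5, 0 with an estimated correlation, 0 with fry and 3 to 7 without 1 library. With an estimated correlation the adjusted p was 0.435 for direct markers, 0.270 for indirect markers, 0.302 for striosome markers, 0.435 for potassium channels and 0.566 for mitochondrially encoded transcripts. With fry it was 0.178, 0.0637, 0.0739, 0.524 and 0.524 in that order. With fry's mixed form it was 0.0121, 0.00469, 0.00469, 0.532 and 0.201 in the same order. Without 1 library it ran from 0.00443 to 0.236 for potassium channels and from 0.00103 to 0.166 for mitochondrially encoded transcripts. The striosome list without genes of the direct pathway list had 0.161. For the indirect and striosome lists the estimated correlation (-0.00538 and -0.0213) lay below the preset 0.01, so a larger correlation did not raise their adjusted p. With an estimated correlation, camera also takes fewer degrees of freedom, which raises p-values by itself. How far this accounts for each change was not measured. Other causes were not tested, apart from the fewer genes or libraries in the reduced fits.

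Same-numbered libraries did not deviate together (correlations across genes of -0.0266 and -0.0381), which gives no sign of a pairing by the titles' numbers. With 2 striatomesencephalic libraries the deviations of that group mirror each other, so this check cannot exclude a pairing. With the replicate number as a block, 0 genes passed, 0 direct and 3 indirect markers passed adjusted over the list alone, and 6 lists passed in place of 5.

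Genes detected in one group only numbered 212 at a threshold of 1 count (97 in striatomesencephalic and 115 in striatopallidal libraries) and 6 at 20 counts (5 and 1), in place of 10 (7 and 3). Of 2332 fold changes of 112 named genes under the alternatives, 2324 kept their sign. The 8 others belong to 6 genes. The other quasi-likelihood settings leave fold changes as in the main fit, and the exact test nearly so, so the share that kept its sign overstates stability. Without 1 library, Chrm4 ran from -0.49 to 1.24, Vcan from -0.96 to 1.28, Gda from -0.13 to 1.39, Dlgap3 from -0.63 to 4.98, Sfxn1 from -1.46 to 0.92 and Cspg4 from -3.81 to 0.28. With quality weights, Sfxn1 was 0.69 and Vcan -0.065. The cause was not tested. In simulated counts with the spread of these libraries, 0 of 98 genes changed 4-fold and 31 of 95 changed 16-fold were recovered, whereas at the same depths and a dispersion of 0.02, 97 of 99 and 97 of 97 were.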

Other observations

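The tests on Gfap's companions, on striatopallidal replicate 2, on the shared fraction and on the number of genes with a small p were chosen only after those results were seen. The simulation used for the shared fraction replaced a chi-square test over the same markers, which had been run first and was then judged unsuited to so few markers. That first test gave a p under 0.05 for both lists. For the indirect list without Ttc12, the change of test moved a shared fraction from argued against to open. For the direct list both tests gave a p under 0.05. Several genes outside the pathway lists had high values in a single library. Dlgap3, a postsynaptic scaffold gene, had 52167 counts in striatomesencephalic replicate 1 against 1129 to 2625 in the others, and was at -0.63 on the log2 scale without that library in place of 4.0. Rps3, a ribosomal protein gene, had 167616 counts in striatomesencephalic replicate 2 against 10491 to 15890. The immediate early gene Nr4a3 stood at 260 ± 7.95 CPM (SD, n = 2) in striatomesencephalic and 58.6 ± 39.8 CPM (SD, n = 3) in striatopallidal libraries and did not pass.

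Markers of each pathway were found in both groups. Penk in striatomesencephalic libraries was at 15.5% of its striatopallidal level, Drd2 at 24.1%, Adora2a at 29.8% and Gpr6 at 47.7%. Drd1 in striatopallidal libraries was at 46% of its striatomesencephalic level, Tac1 at 45.6% and Pdyn at 27.6%. If 1 shared fraction of RNA from the other neuron type were the whole explanation, and the markers were otherwise exclusive, all members of a list would share 1 fold. Direct markers spread more widely than that in simulated counts, at a simulated probability of 0.0355. That spread includes Zfp521 and Sfxn1, which lay on the opposite side of 0, and the Sfxn1 value rested on 1 library. The direct list was not tested without them, so a shared fraction stays open there. All 8 indirect markers also spread more widely (0.002). The 7 without Ttc12, whose mean CPM is under 10, did not (0.304), which leaves a shared fraction open for those 7. Low expression of each gene in the other neuron type also stays open and was not tested.

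Gfap was higher in striatopallidal libraries. More astrocyte RNA in those libraries is argued against as the cause by the other 15 astrocyte markers, whose median log2 fold change was 0.0921 (SD 1.02) where Gfap had -4.56. The spread between amplified libraries stays open. Among 2965 genes with a mean CPM within 2-fold of that of Gfap, 11 had a fold as large. Other groupings of the same libraries gave 8 to 12. This count takes the size of the fold alone, so genes high in a single library count too. It cannot show whether spread alone separates the groups as for Gfap. A difference in the state of astrocytes around the captured cells stays open and was not tested.

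Striatopallidal replicate 2 stood apart from the other libraries: its mean rank correlation with the others was 0.7997, where the other libraries had 0.839 to 0.869. Low depth is argued against, because its total was the highest of the 5, at 1.04 times the next, while it had the fewest genes with at least 10 counts (11871). Fewer captured molecules is a candidate explanation. Of 11443 genes with at least 10 counts in all other libraries, 1.34% had 0 counts in this library. The same share was 0 to 0.23% for the others. Their gene sets differ, because those genes need at least 10 counts in striatopallidal replicate 2. The share thus restates in part its low number of detected genes and is no independent test. More RNA from glia or vessels cannot be told apart, because the outcome turns on the scaling: over the glial and vascular lists with at least 5 tested members, the ratio of its summed CPM to the highest of the other libraries was 0.248 to 0.952 plain and 0.365 to 1.25 TMM-scaled. No biological explanation was tested, because the design gives none for a single library.

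With 2 libraries against 3 there are 10 groupings, too few for a share under 0.05. The mean log2 fold change of direct markers lay 1.94 above that of indirect markers in the real grouping. Taken as a size without regard to sign, this difference was the largest of the 10 (1 of 10), and the largest other was 1.34. Genes with an unadjusted p below 0.05 numbered 839 in the real grouping, and 4 of the 10 groupings gave as many or more. The highest, 1407, put striatomesencephalic replicate 1 with striatopallidal replicate 2, and the 4 include each grouping that sets striatopallidal replicate 2 beside a library other than striatopallidal replicate 1, which points to a structure of the samples around that library.

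The authors' deposited fold changes were matched to within 5.01e-09 by voom on counts divided by the label factors, after which each library is set to its own total again. A factor applied to a whole library nearly cancels in that step. With the label factors applied as normalization factors to the same 12054 genes, fold changes moved by up to 1.39 on the log2 scale, the smallest adjusted p was 0.360 in place of 0.927, and the number of genes past 0.05 stayed at 0. Without any factors the smallest adjusted p was 0.952.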
